A study of Homo sapiens with 15 samples.

How the data were processed

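The data were 15 expression arrays of innate lymphoid cells (ILCs) sorted from human tonsil, 1 array per sample. Per the labels' protocols, tissue was broken up mechanically and filtered, cells bearing CD56 were enriched on magnetic beads, and RNA of each sorted population was extracted with a column kit for small samples. The RNA was amplified with 1 of 2 related kits for small RNA inputs and labelled with biotin, per the labels' protocols, which do not say which array had which kit. The series' design text speaks of biological replicates without naming donors, so that p-values measure the spread between these samples. The header of the table that pairs probes with genes gives the platform, an Affymetrix human gene array.

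The deposited values were probe set intensities on a linear scale, made by the authors with RMA, a method of background correction, normalization and summary that the submitters' processing notes name without a version. That the scale was linear was read from the values themselves; any filter on probes is not given in the sources used here, and neither is a centring or scaling step after RMA. The median intensity was 44.6, 42.2, 43.1 and 45.6 on ILC3a arrays 1 to 4, 44.4, 46.6 and 45.2 on ILC3b arrays 1 to 3, 45.5, 43.6, 45.5 and 47.6 on ILC1b arrays 1 to 4, and 44.0, 43.0, 46.0 and 47.5 on ILC1a arrays 1 to 4. The number of arrays, 3 or 4 in a group, limits the precision.

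Intensities were transformed to log2 with no further normalization and no added constant. The table held 19409 probes, of which 17708 carried 1 gene symbol, 643 several and 1058 none, and genes were named only from probes with 1 symbol. Of these, 17685 were found in a RefSeq gene table by gene number, which changed 0 symbols. Probes of the X-inactivation transcript and of Y-linked genes, 33 in all, were left out before any test because the samples come from persons. For the 598 genes with several probes, the probe with the highest mean over all arrays was used, which left 16902 genes. Genes above the 30th percentile of an array's probes on at least 3 arrays were tested, 12530 in all, and 4372 dimmer genes were not.

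All 15 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with 11 residual and 4.44 prior degrees of freedom). Contrasts were tested 2-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The contrasts were the 3 steps from ILC3a through ILC3b and ILC1b to ILC1a, the difference between the ends, the mean of both transitional populations minus the mean of both ends, and an F test for any difference. Changes are log2 differences with the standard error (SE) of the fit, and group levels are means ± SD of log2 intensity.

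Gene lists were written before the data were examined. Of 19 lists, 18 were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation and with fry as alternatives, and the list of sort markers served as a check of the labels. The other lists covered ILC3 genes, ILC1 and type 1 response genes, cytotoxic granule genes, natural killer (NK) receptors and adaptors, chemokines, tissue residency, circulation and homing, transcription factors, immediate early genes, T cell, B cell, myeloid and epithelial or stromal markers, ILC2 genes, cell cycle, interferon-stimulated, glycolysis and cholesterol synthesis genes. List p-values were adjusted over the 18 lists of a contrast. A gene counts as having risen or fallen in a list when it passed the adjustment over all genes tested.

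Genes named in the text were picked by a rule written before the data were examined. For each contrast it took the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays did not overlap between the groups, up to 3 members with the smallest adjusted p in each list with at least 1 call, the sort markers, and a fixed set of genes for the ends. Probes with several symbols, receptor and immunoglobulin segments, HLA and killer immunoglobulin-like receptor genes, small RNAs and uncharacterised loci were not named. Genes named outside the rule are marked as such or named as under the intensity filter. For the B and T cell markers of the flagged results, the mark stands at the head of that section. Some list members were not analysed here.

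A position was computed for each array along the axis from ILC3a (0) to ILC1a (1), as the projection of its profile on the difference of the end means over genes called between the ends with at least a 2-fold difference. The sort markers were left out, and each end array was compared with end means that excluded it. The positions of ILC1b and ILC3b were compared with a 2-sided exact permutation test. On simulated data of 12530 genes, 97 of 100 genes changed by 2 on the log2 scale and 62 of 100 changed by 1 were called for ILC3b minus ILC3a. For ILC1b minus ILC3b 98 and 59 were called, for ILC1a minus ILC1b 94 and 64, for ILC1a minus ILC3a 98 and 60, and for the transitional contrast 100 and 88. In the same order, 9 of 168, 5 of 162, 14 of 172, 7 of 165 and 12 of 200 calls were genes left unchanged. Simulated values were drawn independently for each gene and array, without the pairs and classes of the real arrays. These counts therefore do not cover such structure.

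Alternatives fixed beforehand were no intensity filter, a filter at the array median, the mean of a gene's probes, the replicate number as a block, fits on only the groups compared, array weights, a trended robust prior, centring of each array, quantile normalization, an added 2-fold threshold, all genes as the axis, and leaving out each array in turn. Chosen after seeing the data were a block for 2 classes of arrays found by clustering deviations from the group means, fits within each class, the 75th percentile of intensity as a covariate, and leaving out ILC1b arrays 2 and 4 together. Also added then were a block on the ILC1b and ILC1a arrays alone and blocked list tests of this comparison with an estimated correlation. The labels do not say that a replicate number marks a donor, so that the numbers were checked by the correlation of deviations from the group means. For ILC1a and ILC1b all 4 pairs with the same number were above 0.1 (0.184 to 0.562), and the blocked values stand beside that result where they changed a call or a count. For the other comparisons of 2 groups, 1 of 3, 1 of 3 and 3 of 4 pairs were. The values carry no detection calls, so that a group mean under the 25th percentile of its arrays counts as dim. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.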

Results

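Gene expression was measured in 4 populations of CD56+ NKp44+ innate lymphoid cells from human tonsil, tissue-resident lymphocytes that lack rearranged antigen receptors. ILC3a cells (4 arrays) were sorted as CD196+ CD300LF+ CD103-, ILC3b cells (3 arrays) as CD196+ CD300LF+ CD103+, ILC1b cells (4 arrays) as CD196+ CD300LF- CD103+, and ILC1a cells (4 arrays) as CD196- CD300LF- CD103+. The series describes the set as transitional populations, so that ILC3b and ILC1b are compared with each neighbour and with the ends of the series. Array medians lay between 42.2 and 47.6 intensity units. The mean correlation of an array with the others of its group, over genes, was lowest for ILC1b array 4 (r = 0.887) and ILC1b array 2 (0.891) and highest for ILC3a array 1 (0.969). These arrays also had the lowest 75th percentiles of intensity, 111.4 and 104.7, against 115.5 to 134.6 on the others. An F test called 718 of 12530 genes as different among the 4 groups.

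Of the 5 genes of the sorted surface proteins, the 4 that were tested followed the labels, and the gene of CD56 was not analysed here. ITGAE, which encodes CD103, measured 4.66 ± 0.16 log2 intensity (SD, n = 4) in ILC3a, 7.84 ± 0.19 (n = 3) in ILC3b, 8.96 ± 0.39 (n = 4) in ILC1b and 8.98 ± 0.28 (n = 4) in ILC1a. CD300LF measured 8.29 ± 0.70 in ILC3a and 7.89 ± 0.63 in ILC3b, against 4.46 ± 0.25 in ILC1b and 4.37 ± 0.35 in ILC1a. CCR6, which encodes CD196, lay between 7.47 and 7.65 in the 3 CD196+ populations and at 4.92 ± 0.68 in ILC1a. NCR2, which encodes NKp44, was lower in ILC1a than in ILC3a (log2 change −0.68, SE 0.19, adjusted p = 0.043), although all populations were sorted as NKp44+. That call was lost in 9 of the 15 fits that left out 1 array, with an adjusted p of up to 0.16 (without ILC3a array 3). ITGAE was higher in ILC1b than in ILC3b (log2 change 1.12, limma adjusted p = 0.0151), although both were sorted as CD103+. Of the 15 fits, 2 lost the ITGAE call.

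The ends of the series differed in cytotoxic and ILC3 genes. Between ILC3a and ILC1a, PRF1, which encodes perforin, rose by 5.37 on the log2 scale (SE 0.29), from 5.95 ± 0.45 to 11.32 ± 0.22 (n = 4 each), and IL22, the cytokine typical of ILC3s, fell by 6.44 (SE 0.54, adjusted p = 8.91e-07). IL23R, a receptor for the cytokine that drives IL-22 production, fell by 6.07 (SE 0.42), from 10.95 ± 0.16 to 4.88 ± 0.61. IFNG, the type 1 cytokine, rose by 5.62 (SE 0.56), from 3.78 ± 0.46 to 9.40 ± 0.54. GZMK, a granzyme gene, rose by 7.75 and KLRF1, which encodes the NK receptor NKp80, by 7.62, from ILC3a levels of 3.20 and 2.72. Those levels, like IFNG in ILC3a and IL22 in ILC1a (3.74), lay under the 25th percentile of the arrays (4.12 in ILC3a and 4.15 in ILC1a), as did the dimmer group of 12 of the 60 named calls, so that these sizes rest on dim probes. In all, 392 genes were higher and 420 lower in ILC1a.

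Of 24 ILC3 genes tested, 18 fell and 0 rose (camera adjusted p = 3.31e-34; 19 fell when adjusted over the list alone). They included the interleukin 1 receptor gene IL1R1 (−5.88, SE 0.33), the protocadherin gene PCDH9 (−5.26, SE 0.33) and the stem cell factor receptor gene KIT (−5.17, SE 0.58). Of 22 ILC1 and type 1 response genes, 13 rose and 2 fell (adjusted p = 7.47e-10; 13 and 2 over the list alone). IKZF3, which encodes the Ikaros family factor Aiolos, rose by 5.02 (SE 0.32), ZNF683 by 4.32 (SE 0.30), EOMES by 3.52 (SE 0.25), FASLG by 3.40 (SE 0.23) and TBX21, which encodes T-bet, by 1.58 (SE 0.17). The members that fell, IL18R1 and TNFSF10, encode a receptor chain for interleukin 18 and a death ligand, and were named after their values were seen. Of 17 cytotoxic granule genes, 10 rose and 0 fell (adjusted p = 2.14e-17; 12 over the list alone), among them GZMA (6.41, SE 0.46), PRF1, NKG7 (5.18, SE 0.28) and CST7 (4.16, SE 0.27). Of 19 NK receptors and adaptors, 9 rose (adjusted p = 9.38e-14; 10 over the list alone), CD160 by 6.05 (SE 0.53) and TIGIT by 3.36 (SE 0.25). Of 19 tissue residency genes, 7 rose and 2 fell (adjusted p = 0.000833; 8 and 2 over the list alone), with CD9 at 3.25 (SE 0.22), TNFRSF9 at 2.22 (SE 0.34) and ADAM19 at −2.08 (SE 0.28). With an estimated correlation, ILC3 genes (adjusted p = 0.000243), the type 1, granule and NK lists (each adjusted p = 0.00979) and the residency list (adjusted p = 0.0289) passed as well.

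Further lists passed with the preset correlation and not with an estimated one. Of 14 circulation and homing genes, 2 rose and 4 fell (adjusted p = 0.0389 and, with an estimated correlation, adjusted p = 0.199; 2 and 5 over the list alone). The interleukin 7 receptor gene IL7R fell by 3.21 and BACH2 by 1.56, while LEF1 rose by 3.00. Of 22 immediate early genes, which tissue dissociation also induces, 4 rose (adjusted p = 0.000429 and, estimated, adjusted p = 0.151), NR4A2 by 1.77, IER3 by 1.43 and DUSP4 by 0.87. Of 23 cell cycle genes, BUB1 (2.22, SE 0.38) and MCM5 (0.75, SE 0.15) rose (adjusted p = 3.64e-08 and, estimated, adjusted p = 0.158; 12 over the list alone). Of 7 ILC2 genes, 2 rose and 1 fell (adjusted p = 0.0185 and, estimated, adjusted p = 0.0597): IL10RA, the interleukin 10 receptor gene, by 4.23, KLRG1 by 1.08, and LPCAT2 by −1.94. That list has 13 genes, and its members IL13, IL5, HPGDS and CRLF2 were under the intensity filter. T cell markers (6 of 12 rose and 2 fell, adjusted p = 0.066), glycolysis genes (0.114) and chemokines (3 of 11 rose and 1 fell, 0.135) did not pass. Neither did epithelial and stromal markers (0.157), cholesterol synthesis genes (0.27), or transcription factors, B cell markers, myeloid markers and interferon-stimulated genes (each 0.731). With fry, however, chemokines (adjusted p = 0.0014) and T cell markers (adjusted p = 0.0407) passed. Single members of the lists that did not pass with camera still changed, CCL4 by 6.28, CCL3 by 3.98 and CCL5 by 3.93. ZEB2 changed by 2.71, MYC by 2.68, ZBTB16 by 1.17, ICOS by −4.04, THEMIS by −3.77, CD27 by 2.48, MS4A1 by 3.03 and BANK1 by −2.81. IFI44 changed by −2.27, OASL by 1.39, GBP2 by 0.81 and ENO2 by 0.71. Among epithelial and stromal markers the median change was 0.06 and the mean −0.54, with EPCAM at −3.55, PECAM1 at −1.42 and FDCSP at −2.44. Among transcription factors the median was −0.02 and the mean 0.16. Other large changes were rises of AOAH (5.78, SE 0.26) and SLAMF7 (5.71, SE 0.45), and falls of ENPP1 (−5.78, SE 0.30), ELAPOR1 (−5.57, SE 0.36) and SPINK2 (−5.18, SE 0.42). Of the 60 named calls of the ends, 55 held whichever array was left out, and KLRG1, FDCSP, ENO2, DUSP4 and NCR2 did not, most often without ILC1a array 3 (4 lost). Within the 2 classes of arrays found by clustering, a setting chosen after seeing the data, 372 and 216 genes were called.

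**Figure D1:**
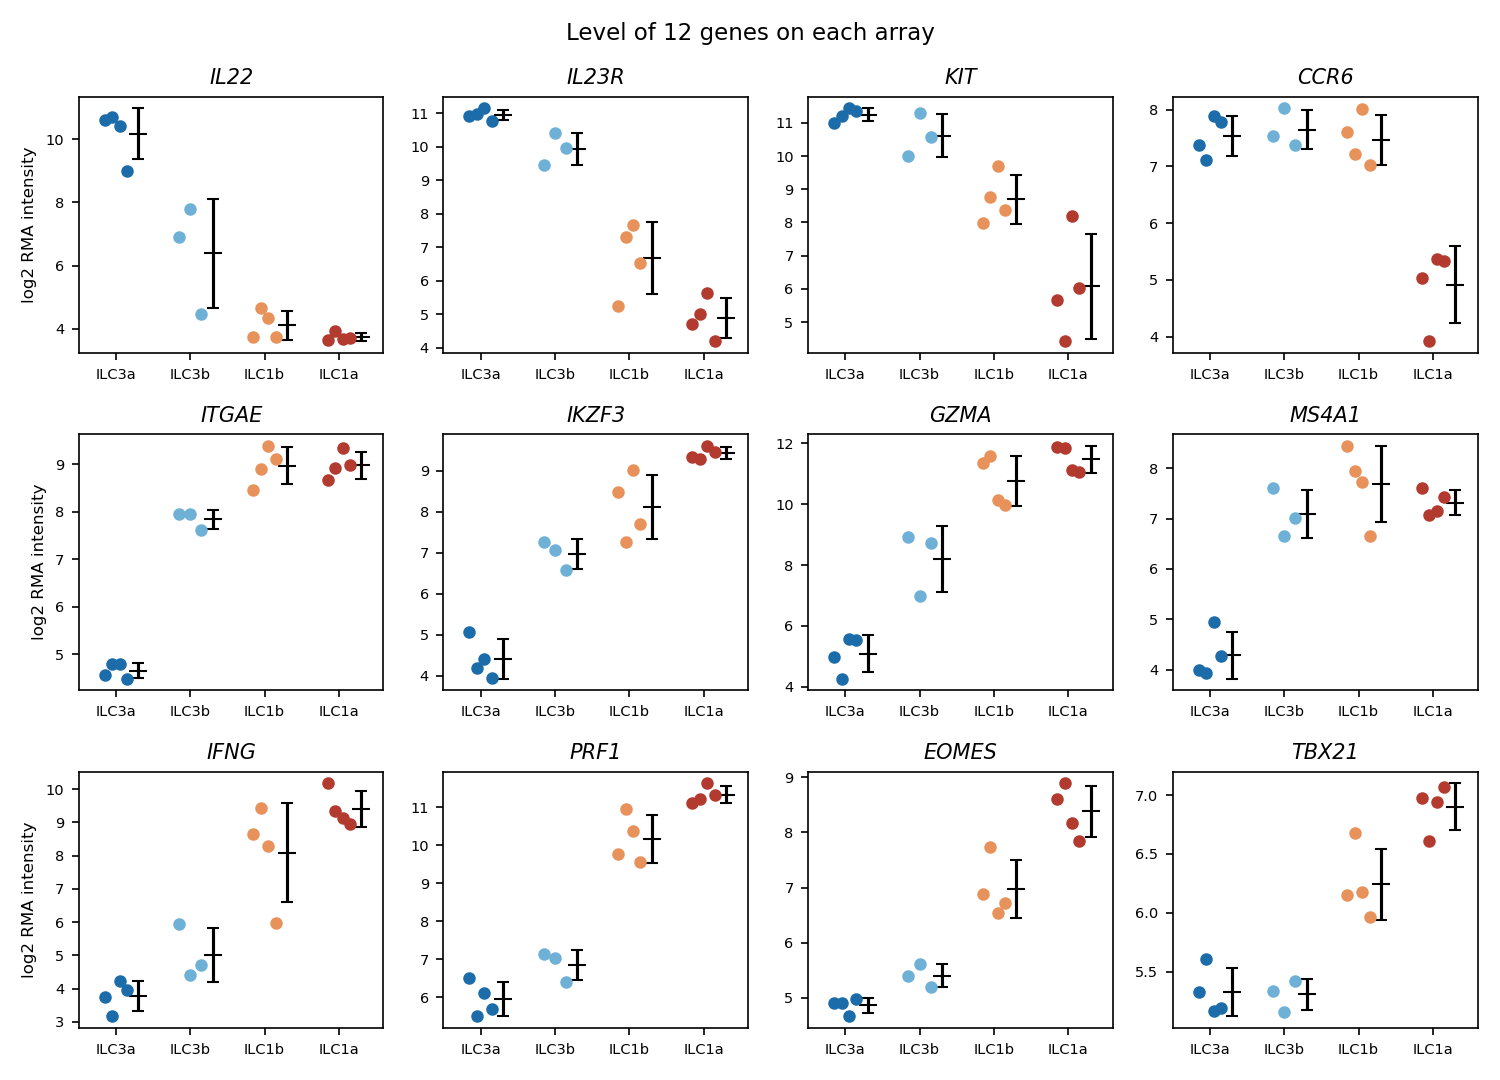
Log2 RMA intensity (vertical axes) of 12 genes on each array (points) of the 4 sorted populations (horizontal axes), with the group mean and SD in black. IL22 stood at 10.18 ± 0.81 in ILC3a and 3.74 ± 0.13 in ILC1a, while PRF1 stood at 5.95 ± 0.45 and 11.32 ± 0.22.

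Gain of CD103 among CD300LF+ cells (ILC3b against ILC3a) came with a lower level of IL22 and higher levels of AOAH, MS4A1 and IKZF3. IL22 fell by 3.79 on the log2 scale (SE 0.58, adjusted p = 0.00725), from 10.18 ± 0.81 (n = 4) to 6.39 ± 1.72 (n = 3). AOAH, a lipopolysaccharide-degrading lipase, rose by 3.17 (SE 0.28) from an ILC3a level of 3.68, under the 25th percentile of the arrays (4.12), MS4A1, which encodes the B cell surface protein CD20, by 2.81 (SE 0.36, adjusted p = 0.00117), and IKZF3 by 2.57 (SE 0.35, adjusted p = 0.00246). TIGIT (2.47, SE 0.27) and CD247 (2.38, SE 0.36), both from the list of NK receptors and adaptors, and the chemokine gene CCL5 (1.78, SE 0.22) rose as well. Of 50 genes called, 31 were higher and 19 lower in ILC3b.

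Other rises were FCRL3 (2.86, SE 0.45), ADGRG3 (2.79, SE 0.31), GZMA (3.14, SE 0.50), the gut-homing receptor gene GPR15 (3.10, SE 0.55) and MS4A6A (3.54, SE 0.71, adjusted p = 0.0409). Smaller rises were KLRF1 (2.49, from a dim ILC3a level of 2.72), CST7 (1.77), CD9 (1.30), and the transcription factor genes MYC (1.42), IRF4 (1.14) and ID3 (1.03). Falls were P2RY14 (−2.60), RAB27B (−2.12), PLXDC2 (−1.86), FRY (−1.68), the potassium channel gene KCNA3 (−1.63, SE 0.19), TRAM2 (−1.61), SVIL (−1.57) and LPCAT2 (−1.23). Among NK receptors and adaptors, 3 of 19 rose (median change 0.79, adjusted p = 1.27e-08; 9 over the list alone), and with an estimated correlation the adjusted p was 0.061. Cytotoxic granule genes (2 of 17 rose, adjusted p = 0.000111 and, estimated, adjusted p = 0.186) moved up. Residency genes (1 of 19, 0.0206 and, estimated, adjusted p = 0.131) and type 1 genes (1 of 22, 0.0381 and, estimated, adjusted p = 0.348) did too. ILC3 genes (1 of 24 fell, 0.00111 and, estimated, adjusted p = 0.166) and circulation genes (0 of 14 passed singly, 0.00141 and, estimated, adjusted p = 0.0942) moved down. T cell markers (0 of 12 passed singly, median 0.36, adjusted p = 0.000318 and, estimated, adjusted p = 0.0942) were higher in ILC3b. B cell markers (1 of 12 rose, median 0.20, adjusted p = 0.00111 and, estimated, adjusted p = 0.061) and immediate early genes (0 of 22 passed singly, 0.0482 and, estimated, adjusted p = 0.417) also moved up with ILC3b. The count of 50 genes fell to 19 without ILC3b array 1, 24 without ILC3b array 3, 31 without ILC3a array 1, and 33 without either ILC3a array 3 or ILC1a array 3. At least 1 such fit lost 16 of the 27 named calls (MS4A6A, GZMA, GPR15, P2RY14, RAB27B, PLXDC2, FRY, TRAM2, SVIL, CST7, KLRF1, CD9, IRF4, ID3, MYC and LPCAT2). Of the 15 fits, 14 lost LPCAT2, 11 lost KLRF1, 11 lost MYC and 10 lost MS4A6A. IL22, AOAH, MS4A1, IKZF3, TIGIT, CD247 and CCL5 were not lost. Fitted on the 7 arrays of both groups alone, 18 genes were called; within the 2 classes of arrays 9 and 0 were (290 at an unadjusted limma p under 0.05 in the latter), where 1 group had a single array, assumed to vary like the other groups.

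Loss of CD300LF among CD103+ cells (ILC1b against ILC3b) came with higher levels of cytotoxic granule genes and lower levels of ILC3 genes. The perforin gene PRF1 rose by 3.31 on the log2 scale (SE 0.31, adjusted p = 5.61e-05), from 6.85 ± 0.39 (n = 3) to 10.16 ± 0.63 (n = 4), and NKG7 rose by 3.04 (SE 0.31). KLRF1 rose by 3.81 (SE 0.49), CCL4 by 3.72 (SE 0.59), the granzyme gene GZMB by 3.31 (SE 0.53) and the residency factor gene ZNF683 by 2.92 (SE 0.32). In the other direction, the cytokine receptor genes IL1R1 (−3.31, SE 0.36) and IL23R (−3.27, SE 0.46) fell, as did those of the transcriptional regulators TLE1 (−2.66, SE 0.29) and TOX2 (−2.99, SE 0.36). In all, 50 genes were higher and 72 lower in ILC1b, a balance that turned without ILC1b array 4 (58 higher, 52 lower).

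Of 24 ILC3 genes, 10 fell and 0 rose (median −1.63, adjusted p = 6.29e-27; 18 over the list alone). Of 17 cytotoxic granule genes 6 rose (median 0.69, adjusted p = 4.8e-12; 9 over the list alone), and of 22 type 1 genes 7 rose (median 0.52, adjusted p = 1.91e-06; 8 over the list alone), FASLG by 2.13 (SE 0.25) and EOMES by 1.57 (SE 0.27). Both passed with an estimated correlation (each adjusted p = 0.0333), as did the ILC3 list (adjusted p = 0.000739). Of 19 NK receptors and adaptors 4 rose (adjusted p = 2.82e-06 and, with an estimated correlation, adjusted p = 0.0762), including CD160 (3.42, SE 0.57) and the Fc receptor gene FCGR3A (2.68, SE 0.50). The ILC2 list passed (1 of 7 rose, adjusted p = 0.00175 and, estimated, adjusted p = 0.0333) with IL10RA at 2.41 (SE 0.26). Its members IL13, IL5, HPGDS and CRLF2 were under the intensity filter, so that the call rests on other members. Cell cycle genes passed with 0 of 23 called singly (adjusted p = 0.00832 and, estimated, adjusted p = 0.596). Of 11 chemokine genes, CCL4, CCL5 (1.84, SE 0.22) and CCL3 (1.99, SE 0.38) rose and 1 fell, with a list median of −0.09 and a mean of 0.32 (adjusted p = 0.224). Further rises were IFNG (3.08, SE 0.61), SLAMF7 (2.93), LEF1 (1.64), ZEB2 (1.28), CD9 (1.28) and GBP2 (0.92), and further falls ENPP1 (−3.47, SE 0.32), ELAPOR1 (−3.34, SE 0.39), SERPINA1 (−3.03, SE 0.37), the chemokine receptor gene CCR4 (−2.85, SE 0.24, to 3.63 in ILC1b, under the 25th percentile of 4.23), IL7R (−1.09) and BACH2 (−1.06). The count of 122 genes fell to 58 without ILC3b array 2 and 63 without ILC3b array 3. At least 1 such fit lost 12 of the 31 named calls (IFNG, CD160, EOMES, FCGR3A, CCL3, CD9, IL7R, LEF1, BACH2, ZEB2, GBP2 and ITGAE), 11 of them without ILC3b array 3. Fitted on the 7 arrays alone 40 genes were called, and within the classes of arrays 1, with a single ILC3b array, and 40. Without ILC1b arrays 2 and 4, whose signal was narrower, 44 were higher and 38 lower, a setting chosen after seeing the data, and another split of the same 7 arrays called 326 genes.

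Loss of CD196 among CD300LF- CD103+ cells (ILC1a against ILC1b) came with lower levels of IL7R, THEMIS and EPCAM. THEMIS, a T cell signalling gene, fell by 3.19 on the log2 scale (SE 0.38), from 8.07 ± 0.55 (n = 4) to 4.87 ± 0.98 (n = 4). EPCAM, an epithelial adhesion gene, fell by 3.97 (SE 0.51, adjusted p = 0.00134) to 2.54 ± 0.58, under the 25th percentile of the ILC1a arrays (4.15), as was the dimmer group of 6 of the 22 named calls. Falls were also seen in SPINK2 (−3.19, SE 0.42), LRRN3 (−2.92, SE 0.35), the costimulatory receptor gene ICOS (−2.49, SE 0.47) and IL7R (−1.84, SE 0.20, adjusted p = 0.000543). DTHD1 rose by 2.55 (SE 0.30), the sialyltransferase gene ST8SIA6 by 2.38 (SE 0.25) and SLAMF8 by 1.47 (SE 0.14). In all, 21 genes were higher and 28 lower in ILC1a, a balance that turned without ILC1b array 3 or ILC1a array 2 (24 higher and 16 lower in each case) and widened without ILC1b array 4 (13 higher, 33 lower). With the replicate number as a block, since the arrays of these groups deviated in pairs, 43 genes were higher and 45 lower, and in a blocked fit on the 8 arrays alone 15 and 15, of which 18 were among the 49.

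Of 24 ILC3 genes, 2 fell, PCDH9 (−2.61, SE 0.33) and the B cell activating factor gene TNFSF13B (−2.01, SE 0.33). The list passed with the preset (adjusted p = 6.02e-11; 1 rose and 8 fell over the list alone) and an estimated correlation (adjusted p = 0.0296). Type 1 genes moved up (2 of 22 rose, adjusted p = 7.34e-07 and, estimated, adjusted p = 0.0538), with EOMES at 1.41 (SE 0.25) and FASLG at 1.25 (SE 0.23). Cytotoxic granule genes (0 of 17 called singly, median 0.52, adjusted p = 7.34e-07 and, estimated, adjusted p = 0.157) and NK receptors (0 of 19, 0.0089 and, estimated, adjusted p = 0.369) were higher. Cell cycle genes (0 of 23, 0.00276 and, estimated, adjusted p = 0.432) and immediate early genes (0 of 22, 0.0388 and, estimated, adjusted p = 0.398) also moved up. T cell markers moved down (2 of 12 fell, 0.012 and, estimated, adjusted p = 0.29). So did B cell markers (1 of 12 fell, BANK1 at −1.88, 0.00393 and, estimated, adjusted p = 0.0643) and epithelial and stromal markers (1 of 12 fell, 0.00164 and, estimated, adjusted p = 0.29). In the blocked fit on the 8 arrays alone, chosen after seeing the data, the ILC3 list did not pass with an estimated correlation (adjusted p = 0.144), and cholesterol synthesis genes passed with the preset (adjusted p = 0.0451, against 0.0672 without the block). With the block on all arrays the cell cycle list had an adjusted p of 1.8e-05 and, estimated, of 0.242, so that its call with the preset alone stayed. Within pairs of the same number, the mean of the ILC3 list was lower in ILC1a in all 4 (−0.95 to −0.57). The granule (0.15 to 1.16), NK (0.15 to 0.90) and cell cycle lists (0.28 to 0.56) were higher in ILC1a in all 4. These differences were not tested, and 4 pairs are few. Other rises were SH2D1A (2.05), RHOBTB3 (1.89), LYST (1.70), SPRY2 (1.64), PSTPIP2 (1.45) and ZEB2 (1.35), and BEX5 fell by 2.33. The count of 49 genes fell to 24 without ILC1b array 1, 20 without ILC1a array 1, 29 without ILC1a array 3 and 23 without ILC1a array 4. At least 1 such fit lost 10 of the 22 named calls (SH2D1A, RHOBTB3, LYST, SPRY2, PSTPIP2, ICOS, EOMES, FASLG, ZEB2 and BANK1). Fitted on the 8 arrays alone 17 genes were called, within the classes of arrays 2 and 5, and with the classes as a block 84 (45 higher, 39 lower).

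**Figure D2:**
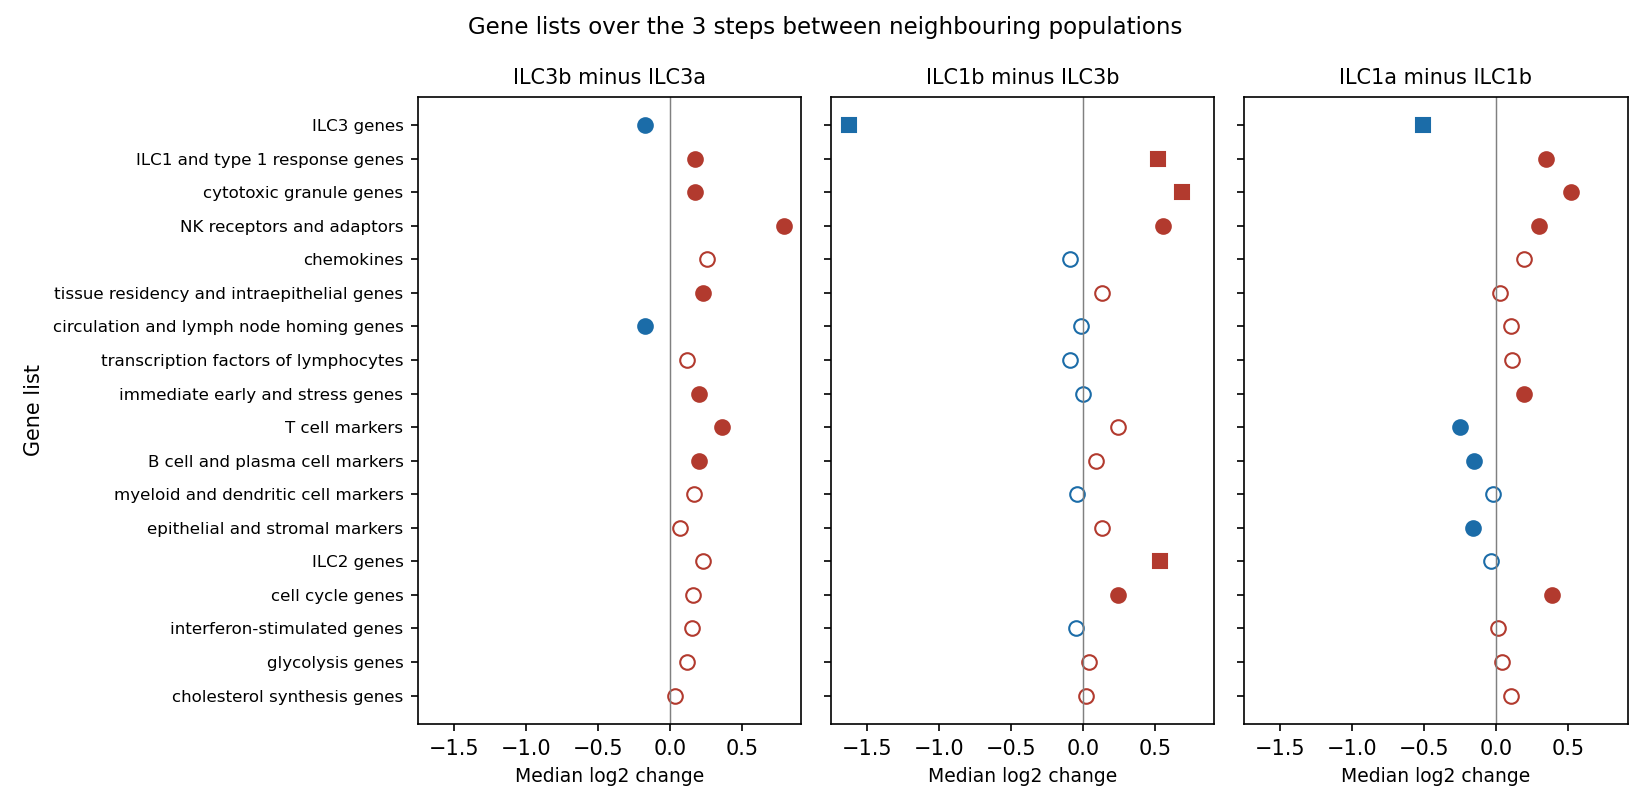
Median log2 change of the tested members of each of the 18 gene lists (rows) for each step between neighbouring populations (panels). Red marks a median above 0 and blue one at or below it, filled symbols passed with the preset correlation, and squares passed with an estimated correlation as well; the ILC3 list stood at −0.18, −1.63 and −0.51 over the 3 steps.

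The mean of the transitional populations differed from the mean of the ends in 66 genes. In 22 of the 12530 genes tested, 13 of them among the 66, every transitional array lay above or below every end array. MS4A6A was higher by 3.02 on the log2 scale (SE 0.48, adjusted p = 0.00781). Its level was 7.98 ± 1.80 (n = 3) in ILC3b and 6.64 ± 1.12 (n = 4) in ILC1b against 4.44 ± 0.85 (n = 4) in ILC3a and 4.14 ± 0.41 (n = 4) in ILC1a, the last under the 25th percentile (4.15), as was a group mean of 4 of the 26 named calls (MS4A6A, DAB2, PCDH9 and EPCAM). MAN1C1, a mannosidase gene, was higher by 1.27 (SE 0.13), the adaptor gene DAB2 by 1.08 (SE 0.20, from dim levels of 3.68 in both ends), the amino acid transporter gene SLC16A10 by 1.03 (SE 0.14), the mucin gene MUC2 by 0.99 (SE 0.14), CD3E by 0.97 (SE 0.17) and RGS10 by 0.68 (SE 0.11). RHOBTB3 (−1.51, SE 0.25), ARAP2 (−1.24, SE 0.13), KCNA3 (−1.01, SE 0.13), KLF7 (−0.97, SE 0.18) and CTBP2 (−0.92, SE 0.13) were lower. In all, 42 genes were higher and 24 lower than the mean of the ends, against 62 and 60 with the replicate number as a block.

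T cell markers were higher in the transitional populations (2 of 12 rose, median 0.51, adjusted p = 9.84e-05 and, with an estimated correlation, adjusted p = 0.106), with THEMIS at 1.85 (SE 0.28). CD3E had means of 11.16 ± 0.26 in ILC3b and 11.14 ± 0.06 in ILC1b, against 10.36 ± 0.30 in ILC1a and a lower level still in ILC3a. B cell markers passed with both correlations (1 of 12 rose, median 0.19, adjusted p = 9.84e-05 and, estimated, adjusted p = 0.0269), with MS4A1 at 1.59 (SE 0.24). Epithelial and stromal markers (1 of 12 rose, EPCAM by 2.05, 0.0304 and, estimated, adjusted p = 0.604) and ILC3 genes (1 of 24 rose, PCDH9 by 1.31, 0.035 and, estimated, adjusted p = 0.604) had a positive contrast because ILC1a was low: the mean level of ILC3 genes was lower in each population than in the one before (8.54, 8.15, 6.56 and 5.75), and that of epithelial and stromal markers was 5.74, 5.72 and 5.71 in the populations before ILC1a, and lower there. THEMIS, EPCAM, PCDH9 and IL7R (0.77) were low in ILC1a, and MS4A1, TIGIT (1.15), CD247 (1.30) and CCL5 (0.74) low in ILC3a, so that for these genes 1 end set the contrast. IRF4 (0.83), ID3 (0.84) and HPGD (1.09) were also higher, and KLF3 (−1.16), EGR1 (−0.80) and ITGAX (−1.28) lower. The count of 66 genes fell to 42 without ILC3b array 1 and 41 without ILC1a array 1. At least 1 such fit lost 12 of the 26 named calls (DAB2, CD3E, KLF7, PCDH9, CD247, CCL5, IL7R, KLF3, EGR1, ITGAX, EPCAM and HPGD). Of these 66 genes, 0 were called within either class of arrays (540 and 442 genes at an unadjusted limma p under 0.05), where ILC3b or ILC3a had a single array.

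Over the genes that separated the ends, the transitional populations took intermediate positions. On an axis of 534 genes from ILC3a (0) to ILC1a (1), ILC3b stood at 0.257 ± 0.064 (SD, n = 3) and ILC1b at 0.730 ± 0.032 (n = 4). The difference was 0.474, with the populations fully apart (2-sided exact permutation test, p = 0.0286, the smallest that the 35 splits can give). The 249 genes higher in ILC1a placed ILC3b at 0.285 and ILC1b at 0.720, and the 285 lower genes at 0.228 and 0.741. Of the 812 genes called between the ends, 520 had group means ordered through ILC3b and ILC1b, and for 415 the largest step lay between ILC3b and ILC1b, against 191 between ILC3a and ILC3b and 206 between ILC1b and ILC1a. These genes were selected for the distance between the ends on the same arrays, which favours means in between. No share expected by chance was computed for these counts. TBX21 took no part in the first step, at 5.32 ± 0.20 in ILC3a, 5.31 ± 0.14 in ILC3b, 6.24 ± 0.30 in ILC1b and 6.90 ± 0.20 in ILC1a. Without any 1 array of ILC3b or ILC1b the smallest p the splits allow is above 0.05. Within the classes of arrays the difference was 0.439 and 0.479. These positions were read off the axis of all arrays, on which the populations did not overlap. The values within the classes are therefore no separate check.

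**Figure D3:**
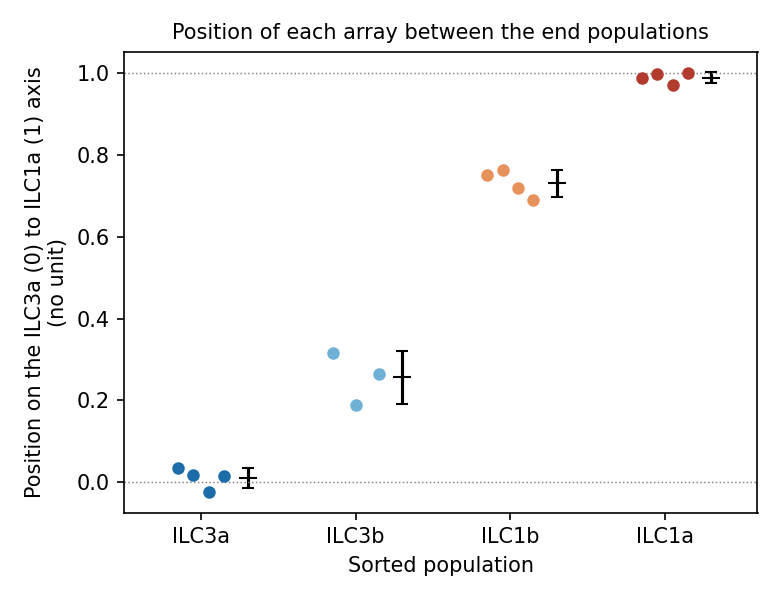
Position of each array (points) of the 4 sorted populations (horizontal axis) between the mean ILC3a profile (0) and the mean ILC1a profile (1) over 534 genes (vertical axis, no unit), with the group mean and SD in black. The ILC3b arrays lay between 0.189 and 0.317 and the ILC1b arrays between 0.690 and 0.762.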

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

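The tests of MS4A1, of the CD3 genes, of the replicate numbers and of the percentile range of the array classes were chosen after their results were seen. Most B and T cell markers named with these tests were not picked by the naming rule, and were named after their values were seen. The covariate test of the 75th percentile was chosen after its split and the percentiles were seen, though before its own count. Chance was excluded by the splits of the arrays for ILC3b minus ILC3a, where 1 of 35 splits, the real one, gave 50 genes and the highest other gave 2. The same held for ILC1a minus ILC3a (1 of 35, 812 against 1), though these splits ignore the replicate numbers. Of its 4 pairs with the same number, 3 had deviations correlated above 0.1. The contrast of ILC3b and ILC3a is partly mixed with the classes of arrays. ILC3a held 3 arrays of class 1 and 1 of class 2, and ILC3b held 1 and 2. The split of these 7 arrays that followed the classes fully called 0 genes. Chance was excluded as well for the F test (1 of 100 relabellings drawn, 718 against 150). For the transitional contrast 2 of 100 relabellings gave at least 66 genes, a share under 0.05. The other of these gave 85, more than the real grouping, so that chance was made unlikely and not excluded. Free relabelling, though, ignores the pairs and mixes the ends. Forms that keep more of the design were added after those counts were seen. Exchanging groups only within a replicate number, 1 of 100 draws gave 718 genes by the F test (highest other 578), and 2 of 100 gave 66 transitional genes. The other gave 419, and it set the intact ILC1a group against the intact ILC3a group, so that it holds the difference of the ends. Exchanging only ILC3a with ILC3b arrays, and ILC1a with ILC1b arrays within a pair, 1 of 100 draws gave 66 genes (highest other 52). In that form 1 of 100 gave 22 genes without overlap of transitional and end arrays (highest other 6). As many genes without overlap came in 3 of 100 free relabellings (highest other 92) and in 2 of 100 exchanges within a replicate number (highest other 35). Chance was not excluded for ILC1b minus ILC3b, where 2 of 35 splits gave at least 122 genes and the other gave 326. For ILC1a minus ILC1b, whose arrays deviated in pairs, the splits that part all 4 pairs, 8 in number, are too few for a share under 0.05: the real one gave 49 genes and 9 lists, and the highest other 1 gene and 5 lists. Over all splits, most of which part fewer pairs, 1 of 35 gave as many genes (49 against 1) and 1 of 35 as many lists (9 against 7). For counts of lists, chance was not excluded for ILC3b minus ILC3a (3 of 35, 9 against 9), ILC1b minus ILC3b (6 of 35, 6 against 8), ILC1a minus ILC3a (3 of 35, 9 against 12) or the transitional contrast (28 of 100, 4 against 13).

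The split with 326 genes set ILC3b array 3 with ILC1b arrays 2 and 4 against the other 4 arrays, which points to a structure of the arrays that the groups do not give: these 3 had 75th percentiles of intensity of 104.7 to 120.5, against 127 to 132.1. With the percentile as a covariate the split called 1 gene and the real grouping 111 in place of 122, but the fall is partly built in, since the sides do not overlap in the percentile (correlation 0.865 with the split), so that breadth of signal as its source cannot be told apart from another difference between these arrays. Clustering of deviations from the group means also parted the 15 arrays into classes of 8 and 7. The percentile did not separate them: 5 of the 7 lay in the range of the 8, which argues against that percentile as the cause of the classes. The array medians, set beside the classes after they were seen, came close to separating them. They ran from 42.17 to 45.49 in the 8 and from 45.22 to 47.63 in the 7, so that a link of intensity with the classes stays open. In 13 of the 15 arrays the class went with a replicate number of 1 or 2 against 3 or 4, so that donors, processing days and the amplification kits, none of which the labels tie to arrays, cannot be told apart. No biological explanation was tested for this structure.

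MS4A1 was higher in ILC3b than in ILC3a by 2.81 (95% interval 2.05 to 3.56). B cells among the sorted cells would raise other B cell genes as well, and the other 11 markers tested had a median change of 0.18 (SD 0.47 over markers), with CD79A at 0.11, CD79B at −0.02 and PAX5 at 0.18, which argues against them as the cause. The markers JCHAIN and FCRL1, at 1.42 and 1.05, stood above the rest without passing the test. As a whole the B cell list, MS4A1 included, moved up in this step (camera adjusted p = 0.00111 and, estimated, adjusted p = 0.061). MS4A1 was also picked for its large rise, so that smaller changes of the other markers were likely beforehand. A trait of the CD103+ populations would place ILC1b and ILC1a high too, and the lowest of their arrays lay 1.70 above the highest ILC3a array. That MS4A1 belongs to the CD103+ state is a hypothesis found and tested on these data, and cross-hybridisation of its probe was not tested.

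CD3D, CD3E and CD3G were on average 1.22 higher in ILC3b than in ILC3a (SE 0.32, 95% interval 0.53 to 1.91). The test assumed that T cells among the sorted cells would raise other T cell genes by about as much. A log2 rise also depends on a gene's level beforehand, which the test did not take into account. The other 9 markers tested had a median change of 0.10 with a wide spread (SD 0.63), so that the test decided neither for nor against T cells. Of these, TRAT1 (1.58) and CD27 (1.09) moved with the CD3 genes, while CD2 (0.04), CD5 (0.02) and CD8A (0.03) stayed near 0 and ICOS stood at −0.51. A first form of the test, on CD4, CD5, CD6, CD8A and CD28 alone, gave 0.02, but those 5 had been picked after their values were seen and it was dropped. T cells and expression of CD3 chains by the ILCs themselves cannot be told apart here, since T cell receptor constant genes were not analysed here.

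In 378 groups of 4 arrays tested for a single array far from the rest, 20 were found, where chance gives 18.9 (about 1 in 20 groups), and the 17 among the named genes compare with 15.6 by chance. The 75th percentile of intensity was 119.5 on ILC3a array 2, against a mean of 129.4 on the others of its group. The mean of the NK receptor list was 8.59 on ILC1b array 4, and that of the chemokine list 7.30 on ILC3a array 1. In ILC3a, log2 intensities far from the other arrays were IFI44 at 9.08 and LRRN3 at 7.83 (array 3), IL22 at 8.99 and LYST at 6.61 (array 4), RAB27B at 7.59 (array 1) and TNFRSF9 at 5.30 (array 2). In ILC1b they were EGR1 at 10.07, KLF3 at 6.83 and PCDH9 at 5.19 (array 2), and FCRL3 at 9.52 and ID3 at 6.09 (array 1). In ILC1a they were CCR4 at 2.96 (array 4), KLF7 at 8.08, MAN1C1 at 6.63 and NKG7 at 12.25 (array 2), and SLAMF7 at 10.90 and ST8SIA6 at 6.75 (array 1).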

How the results depend on the processing

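The class, percentile, ILC1b array, 8-array block and blocked estimated-correlation settings were chosen after seeing the data. Of the named calls, 0 changed sign in 30 settings, and 111 of 166 named calls held whichever array was left out. The steady sign is partly built in, since the rule took the largest changes only from genes without overlap between the groups. Leaving out arrays cannot turn the sign of such a gene. With array weights, counts rose to 202 (ILC3b minus ILC3a; 105 higher and 97 lower, against 31 and 19), 428 (ILC1b minus ILC3b), 166 (ILC1a minus ILC1b), 1395 (ILC1a minus ILC3a), 214 (transitional) and 1394 (F test) genes, while lists went to 5 and 10 for the first 2 steps; the cause was not tested. Centring gave 30 higher and 27 lower genes for ILC3b minus ILC3a, and 23 and 43 for ILC1a minus ILC1b (21 and 28 without it). Fits on only the groups compared gave 18 (14 higher, 4 lower), 40 and 17 genes for the 3 steps, and 965 for the ends; the cause was not tested. A 2-fold threshold left 537 genes between the ends and 39 in the transitional contrast. With an estimated correlation 0, 1, 5 and 1 lists passed for ILC3b minus ILC3a, ILC1a minus ILC1b, the ends and the transitional contrast. In the same order fry called 4, 3, 11 and 2. The replicate block gave 88 genes for ILC1a minus ILC1b (30 in a fit on those 8 arrays, where the ILC3 list no longer passed with an estimated correlation and cholesterol synthesis genes passed with the preset) and 122 for the transitional contrast (62 higher, 60 lower). It kept every other count within 1.5 times and changed no other list call of ILC1a minus ILC1b. Of all 21 pairs of arrays with the same number 14 had deviations correlated above 0.1 (median 0.223, lowest −0.292), and 12 of 15 arrays correlated best with their own number, a hint from the data, not the design. For ILC1a minus ILC1b, the class block gave 84 genes and the covariate of the 75th percentile 75 (23 higher, 52 lower). Without ILC1b arrays 2 and 4, 10 lists passed for ILC1b minus ILC3b, and the position difference was 0.472 (exact p = 0.1, the smallest possible). Within class 1 and class 2, which hold fewer arrays, limma called 9 and 0, 1 and 40, and 2 and 5 genes for the steps (290 at an unadjusted p under 0.05 where 0 passed) and 372 and 216 for the ends. They gave 0 and 0 (540 and 442 at an unadjusted p under 0.05) for the transitional contrast and 227 and 179 for the F test, and the position difference 0.439 and 0.479. Leaving out 1 array gave 19 to 56, 58 to 123 and 20 to 73 genes for the steps, 612 to 913 for the ends, 41 to 96 for the transitional contrast and 550 to 762 for the F test. The lists ranged over 8 to 11, 5 to 7, 7 to 10, 7 to 10 and 2 to 6, the 2 coming without ILC3a array 4 or ILC3b array 3, and the position difference over 0.440 to 0.505. Without the intensity filter, which brings in dim genes, every count of genes and lists stayed within 1.5 times.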

Other observations

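These genes were singled out after their values were seen. MS4A6A was highest in the transitional populations, at 4.44, 7.98, 6.64 and 4.14 in ILC3a, ILC3b, ILC1b and ILC1a, and its spread was widest in ILC3b (SD 1.80, n = 3). MAN1C1 had the same course with less spread, at 6.61 ± 0.28, 8.19 ± 0.16, 7.88 ± 0.28 and 6.92 ± 0.19. ARAP2 took the opposite course, at 7.12 ± 0.16, 5.98 ± 0.33, 6.46 ± 0.22 and 7.78 ± 0.26. CD8A, which was not picked by the rule and was named after its values were seen, stood at 4.85 in ILC3a and 6.52 in ILC1a, a change of 1.67.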
